A study of Homo sapiens with 3 samples.

How the data were processed

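Each of 3 groups, CAL 27 cells carrying the vector, nm23-H1 or nm23-H2, was measured on 1 Affymetrix array of 22283 probe sets. The deposited values are linear intensity signals per probe set, made with MAS5 according to the submitters' processing notes, in which neither the version nor the scaling target is stated and no detection calls are given. No common target showed in the values: means between the 2nd and 98th percentiles were 85.9 for nm23-H1, 100.0 for nm23-H2 and 79.6 for vector. Each array was multiplied (by 1.03, 0.881 and 1.11) to bring that mean to the geometric mean of the 3. Values below the pooled median of 28.3 were set to this floor, and log2 was taken. For each gene 1 probe set was used among the 19071 annotated to a single symbol: those not ending in _x_at first, then the brightest on average. The 1043 probe sets with several symbols and the 2169 with none were left out, except the one shared by NME2 and the NME1-NME2 read-through. A gene was measured when its probe set was above the floor on at least 1 array. A fold against an array at the floor is a bound.

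Genes were counted when the difference was at least 1 on the log2 scale (2-fold). With 1 array per group no test across samples was possible. Probe error was the SD of the difference between the log2 differences of the brightest 2 probe sets of a gene, divided by the square root of 2, and covers neither cultures, transfectants nor hybridisations. The 41 gene lists, the choice of settings, the comparisons and the rule for named genes were fixed before the data were examined. A list's median difference was ranked among 10000 random lists of the same size matched on mean expression in 20 bins, and it stood apart below percentile 2.5 or above 97.5. Lists with fewer than 5 measured genes were given as values. The 123 list comparisons were not corrected for their number.

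Named genes were NME1 and NME2, the 12 largest higher and 12 largest lower for each comparison with vector, 6 and 6 for nm23-H1 against nm23-H2, 5 and 5 per array set apart, and up to 4 members per list with the largest difference. The largest were taken among genes whose brighter array reached the 70th percentile (66.2 signal units) and none of whose other probe sets went the other way by 0.5 or more. The lists were drawn up from general knowledge. Probe set annotation and gene order came from the reference tables, the order and positions from assembly GRCh38.p14. Blocks of genes are given from the start of the first gene to the furthest end of any gene in them. The test of chromosome windows was added after array-level values had been seen and before differences between genes were computed: medians of 50 neighbouring genes, after the all-gene median was subtracted, were set against the 95th percentile of the largest window median in 1000 shuffles of gene positions.

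Alternatives were the values as deposited, a common median of the values above the floor, quantile normalization, floors at the 25th and 70th percentiles, 16 added in place of a floor, the mean of a gene's probe sets, only probe sets specific by name (ending in plain _at), a threshold of 1.5, the mean for a list's median, and unmatched random lists. Added after seeing the data were leaving out the nm23-H2 array and leaving out the genes of shifted chromosome blocks.

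The steps were tested on simulated data with the measured probe error. Of 500 genes planted at 2-fold, 39.2% were called for nm23-H1 against vector, 35.6% for nm23-H2 against vector and 37.4% for nm23-H1 against nm23-H2, and of those planted at 4-fold 77.6%, 78.8% and 82.2%. Unchanged genes called numbered 17.4, 39.7 and 71.4 on average. The simulated error was the same at all signal levels and came from probe sets above the floor on both arrays. With the floor at the 25th percentile the measured probe error was 0.51, 0.53 and 0.57, so false calls near the floor may be more numerous. Of lists without a shift, 3.5%, 5.5% and 5.5% stood apart, and of lists shifted by 0.5, 100%, 100% and 99.5%. A window passed its bound in 2, 1 and 0 of 20 simulations without a shift, and a planted block of 100 genes was recovered in 20 of 20 for each comparison. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.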

Results

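Transcript levels were measured in CAL 27, a cell line from a squamous cell carcinoma of the tongue, carrying 1 of 3 transfected constructs. The label of the nm23-H2 array does not state whether its transfection was stable. The constructs were the EGFP expression vector alone, the same vector with nm23-H1, and the same vector with nm23-H2. Nm23-H1 and Nm23-H2, encoded by NME1 and NME2, are nucleoside diphosphate kinases, and NME1 is known as a metastasis suppressor gene. Each construct was represented by 1 array of 22283 probe sets, so no group had a replicate, no difference had a replicate check, and no p-value was computed. Construct and transfected cell line coincided on every array, so a difference between arrays is also a difference between separately grown transfectants. The deposited signals had medians of 29.6 on the nm23-H1 array, 29.0 on the nm23-H2 array and 26.5 on the vector array. After scaling, 51.6%, 47.4% and 50.9% of their probe sets lay above the floor of 28.3 signal units. Of 11963 genes with a probe set of their own, 8000 were above the floor on at least 1 array. The number of arrays limits the precision, and the only error that could be measured was the disagreement between probe sets of the same gene. That error had an SD of 0.33 (log2) for nm23-H1 against vector, 0.37 for nm23-H2 against vector and 0.40 for nm23-H1 against nm23-H2.

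The transcripts of the transfected genes were higher on the matching arrays. The NME1 probe set gave 2379 signal units on the nm23-H1 array, 1132 on the nm23-H2 array and 1519 on the vector array, which was 1.57-fold the vector level with nm23-H1 and 0.745-fold with nm23-H2. The probe set annotated to NME2 and to the NME1-NME2 read-through transcript gave 2323, 4845 and 2272 signal units on the same arrays, which was 1.02-fold the vector level with nm23-H1 and 2.13-fold with nm23-H2. NME3, a further nucleoside diphosphate kinase gene, was 2.39-fold the vector level with nm23-H1 and 2.94-fold with nm23-H2. NME4 and NME6 differed from the vector by less than 2-fold on both arrays, and NME5 and NME8 were below the floor on all 3. Each of NME1 and NME2 had 1 probe set, and it is not known whether its probes lie within the transfected sequence.

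**Figure D1:**
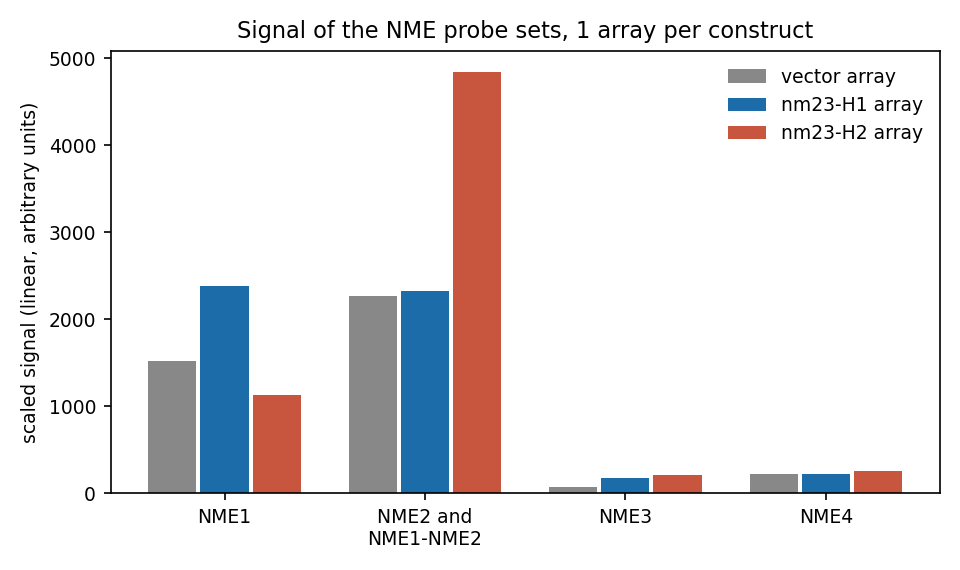
Scaled signal (array signal units) on the vector, nm23-H1 and nm23-H2 arrays, 1 bar per array and probe set. The probe sets are those of NME1, of NME2 with the NME1-NME2 read-through, of NME3 and of NME4. NME1 was brightest on the nm23-H1 array at 2379, and the NME2 probe set was brightest on the nm23-H2 array at 4845.

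The comparison of nm23-H1 with vector addressed the study's titled question, the downstream targets of Nm23-H1. Most genes of epidermal differentiation were lower with nm23-H1, 20 of 28 measured, while 5 were higher. The higher ones included the keratin genes KRT13 (1806 against 963 signal units) and KRT4 (1001 against 778). SPRR1A, SPRR3 and SPRR1B, small proline-rich proteins of the cornified envelope, were 12.6-fold, at least 10.0-fold and 6.67-fold lower. PI3, the elastase inhibitor elafin, was 13.6-fold lower (104 against 1420 signal units), and S100A9 and S100A7, calcium-binding proteins of stressed keratinocytes, were 5.71-fold and at least 4.13-fold lower. S100A8, the partner of S100A9, was 8.33-fold lower by the probe set used, while its other probe set was at the floor on both arrays and gave no difference. On the other side, PYGB, the brain form of glycogen phosphorylase, was at least 5.61-fold higher, and ALPP, placental alkaline phosphatase, was 5.27-fold higher.

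In all, 173 genes were at least 2-fold higher and 137 at least 2-fold lower with nm23-H1 than with vector, together 3.88% of the 8000. Of these, 45 and 42 were bounds because the dimmer array was at the floor. The other genes among the 12 largest higher were HCLS1 (5.18-fold), ENTPD6 (4.67-fold), BMP2, a bone morphogenetic protein (at least 4.40-fold), MMP13, a collagenase (at least 3.92-fold), HSPB8, a small heat shock protein (at least 3.69-fold), THBD, thrombomodulin (3.54-fold), ZXDC (at least 3.51-fold), CALB1, a calcium-binding protein (3.47-fold), SEC23B (3.43-fold) and ERMP1 (3.31-fold). The other genes among the 12 largest lower were VEGFA, an angiogenic growth factor (at least 6.41-fold), SBF1 (4.63-fold), DUSP6, a phosphatase of ERK (4.57-fold), PLAC8 (4.32-fold) and HBEGF, a ligand of the EGF receptor (at least 3.99-fold). Further probe sets gave smaller differences, under 2-fold for CALB1 (0.93), VEGFA (median -0.45), SBF1 (median -0.49), DUSP6 (median -0.81) and HBEGF (-0.84), and 1.38 for BMP2. With the nm23-H2 array left out, another probe set was chosen, and VEGFA differed by -0.36 and DUSP6 by -0.96. Of genes with a further probe set above the floor on both arrays, 57 were at least 2-fold different, and for 49 of them (86.0%) the further probe set went the same way.

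Of 38 gene lists that could be ranked, 8 stood apart from random lists of matching expression, 1 higher and 7 lower with nm23-H1. Random lists would give 1.9, but the lists here share members and their genes may vary together, so 1.9 is no measure of chance for them. The epidermal differentiation list had a median difference of -0.57 (log2), lower than in all 10000 random lists, with 10 of 28 measured genes at least 2-fold lower and 0 higher. The list of matrix proteases and their inhibitors had a median of -0.28, also lower than in all random lists, with 6 of 32 genes at least 2-fold lower and 1 higher. Its lower members included SLPI, a secreted protease inhibitor (3.05-fold), and PLAU, urokinase (2.29-fold), whereas MMP13 was the gene that was higher. Ligands and feedback genes of the EGF receptor had a median of -0.34 (percentile 0.16), and 4 of 16 were at least 2-fold lower, namely DUSP6, HBEGF, ETV4 (at least 2.58-fold) and DUSP5 (2.42-fold). That call was lost with the floor at the 70th percentile. Mesenchymal genes had a median of -0.28 (percentile 0.590), with SPARC, a matrix glycoprotein, 3.26-fold lower and VIM, vimentin, at least 2.55-fold lower among 12 measured. The mesenchymal call was lost with a floor at the 25th percentile, with 16 added in place of a floor, and with probe sets specific by name.

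A further 4 lists stood apart. Genes of ribosome biogenesis and MYC targets had a median of -0.34 (percentile 0.02), with 16 of 20 below 0 and 0 at least 2-fold different, and NPM1, nucleophosmin, was 1.67-fold lower. Immediate early genes, which respond first to growth factors, had a median of -0.34 (percentile 0), with 13 of 19 below 0 and 0 at least 2-fold different, and FOSL1 and KLF4 were each 1.98-fold lower. Integrins and hemidesmosome genes had a median of -0.23 (percentile 2.23), with DST, a hemidesmosome plakin, 2.25-fold lower and ITGA5, an integrin chain, 2.14-fold lower among 13. Interferon response genes stood higher with a median of 0.22 (percentile 99.5), and IRF7 (2.33-fold) and USP18 (2.13-fold) were the 2 of 31 at least 2-fold higher. IRF7 was under 2-fold with the floor at the 70th percentile (0.48 log2) and with 16 added in place of a floor (0.96). With probe sets specific by name the interferon and immediate early calls were lost, and the integrin call was lost with either other floor, with the mean of all probe sets and with unmatched random lists. Genes linked elsewhere to Nm23-H1 and metastasis did not stand apart (median -0.07, percentile 17.1), although MET, the receptor of hepatocyte growth factor, was 2.14-fold lower and GSN, the actin-severing protein gelsolin, 2.10-fold lower among 13. By the mean of a gene's probe sets the differences were under 2-fold for MET (-0.40), GSN (-0.53), DST (-0.15), SPARC (-0.85), SBF1 (-0.64) and HBEGF (-0.94), and SEC23B was at 0.70 by a probe set specific by name. With the floor at the 70th percentile, 30 of the 73 genes that the naming rule took at 2-fold or more were under it.

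Neighbouring genes on several chromosomes shifted together on the nm23-H1 array relative to vector. The 96 measured genes from NRSN2 to GSS on chromosome 20 (347111 to 34956027 in assembly GRCh38.p14) had a median of 0.61, and 40 of them were at least 2-fold higher and 0 lower. The 104 genes from KANK1 to SLC28A3 on chromosome 9 (470295 to 84368727) had a median of 0.40. Lower blocks lay on chromosome 14 (EMC9 to PNMA1, 24138965 to 73714384, median -0.28, and NEK9 to FAM30A, 75079353 to 106879844, median -0.35) and chromosome 22 (SRRD to ARSA, 26483877 to 50628152, median -0.26). The chromosome 14 blocks had medians of -0.27 and -0.33 with nm23-H2 as well, and those of nm23-H1 against nm23-H2 were 0 and -0.02. Such windows held 89 of the 310 genes at least 2-fold different, or 28.7%, against 7.23% of all genes placed on a chromosome, and 83 (26.8%) differed in the window's direction. Among the 12 largest higher genes, PYGB, ENTPD6, BMP2, THBD and SEC23B on chromosome 20 and ERMP1 on chromosome 9 lay in such windows. Of the 12 largest lower, SBF1 on chromosome 22 was the only 1 that did. However, 6 of these 12 were on chromosome 1, namely SPRR1A, SPRR3, SPRR1B, S100A7, S100A8 and S100A9. Whether these 6 lie together was not tested, and a cluster much shorter than a window need not shift the window's median. With the block genes left out, 115 genes were at least 2-fold higher and 106 lower. The split was 212 to 92 with the values as deposited, 653 to 552 with the floor at the 25th percentile and 72 to 59 with the floor at the 70th, and the share in shifted windows in their direction was 9.88% and 47.3% with these floors and 16.6% with 16 added in place of a floor.

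**Figure D2:**
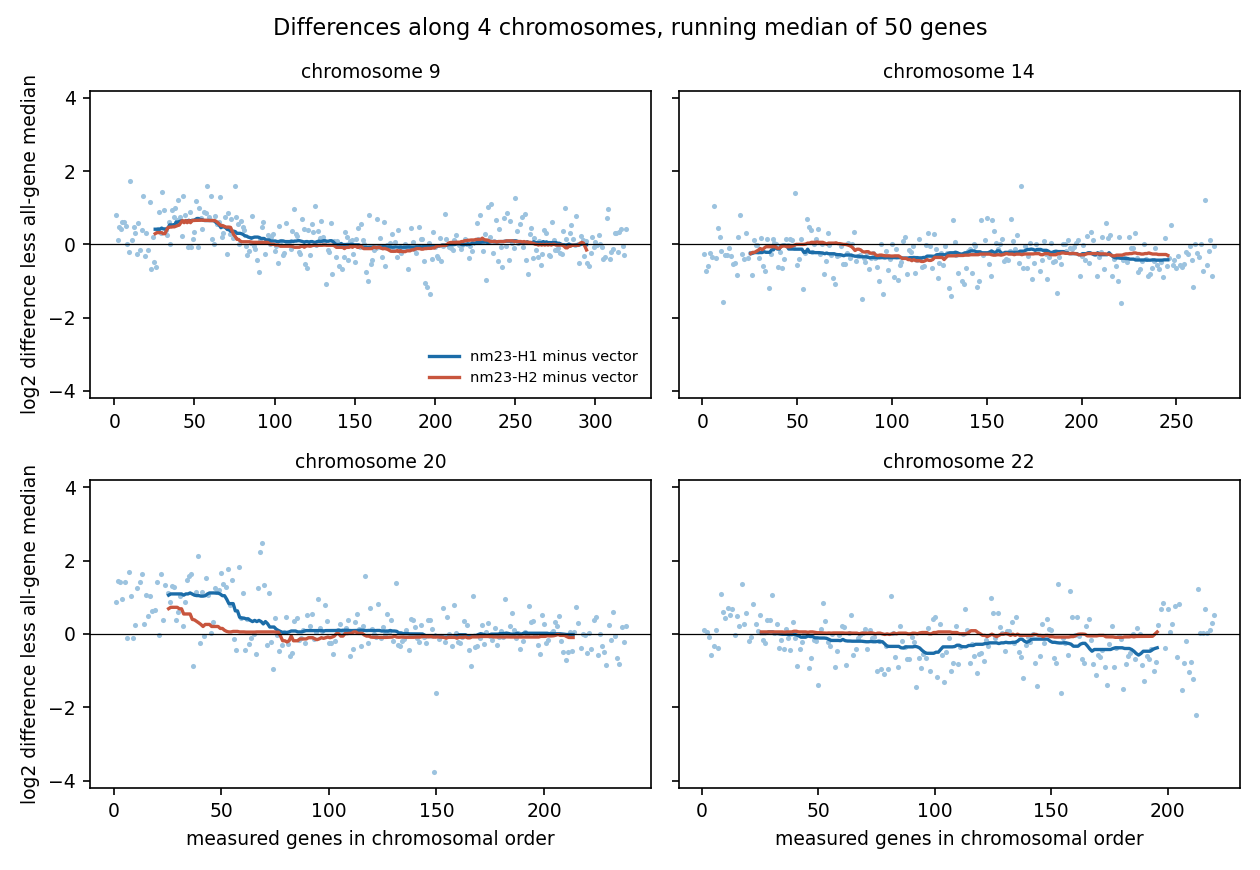
Log2 difference from vector, less the median of all genes, along chromosomes 9, 14, 20 and 22 in gene order, with points for single genes with nm23-H1 and lines for the running median of 50 neighbouring measured genes with nm23-H1 and nm23-H2. On chromosome 20 the running median with nm23-H1 reached 1.12 near the start and that with nm23-H2 reached 0.73.

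The nm23-H2 array was named by its label alone, outside the described design, and its comparison with vector showed how the second isoform's transfectant differed. Genes of the unfolded protein and ATF4 response, which cells switch on when proteins misfold or amino acids run short, were higher with nm23-H2. TRIB3 was 11.3-fold higher, HERPUD1 7.58-fold (1406 against 186 signal units), DDIT3, which encodes CHOP, 5.64-fold, and HSPA5, the chaperone BiP, 5.11-fold (3865 against 757). Genes driven by NF-kB were also higher, with TNFAIP3, its feedback inhibitor, 10.9-fold, and the cytokine genes IL1A and IL1B 5.11-fold and 4.35-fold. KRT4 and KRT13, the keratin pair of mucosal epithelium, were lower by at least 27.4-fold and by 9.14-fold. A further probe set of KRT4, barely above the floor on the vector array and at the floor with nm23-H2, gave a difference of -0.09.

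In all, 283 genes were at least 2-fold higher and 290 at least 2-fold lower with nm23-H2 than with vector, together 7.16% of the 8000, of which 49 and 85 were bounds. The other genes among the 12 largest higher were PYGB (at least 15.3-fold), CALB1 (9.09-fold), LCN2, an iron-scavenging lipocalin (8.33-fold), PHLDA1 (7.95-fold), C3, complement component C3 (at least 7.31-fold), HBEGF (6.45-fold), RHCG, an ammonium transporter (at least 6.37-fold), SERPINB1 (6.30-fold) and TNIP1, a partner of TNFAIP3 (5.90-fold). The other genes among the 12 largest lower were PLAC8 (10.1-fold), GSTM3, a glutathione transferase (-2.85 log2), NUP62 (at least 6.55-fold), MMP1, a collagenase (6.54-fold), SPARC (6.08-fold), CYP1A1, a xenobiotic-metabolising oxidase (6.05-fold), STMN1, a microtubule-destabilising protein (5.69-fold), MMP10 (at least 5.53-fold), GPNMB (4.88-fold) and ID3 (at least 4.42-fold). Further probe sets gave smaller differences for NUP62 (-0.36), PHLDA1 (median 1.55), SERPINB1 (1.84) and TNFAIP3 (2.60). For 83 of 92 such genes with a further probe set (90.2%), it went the same way.

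Of the 38 ranked lists, 20 stood apart with nm23-H2, 15 higher and 5 lower. The unfolded protein and ATF4 list had a median of 0.84, with 13 of 27 genes at least 2-fold higher and 0 lower. NF-kB cytokines and chemokines had a median of 0.91, with 8 of 17 at least 2-fold higher and 1 lower. EGF receptor ligands and feedback genes had a median of 0.65, with 7 of 16 at least 2-fold higher, among them IER3 (3.99-fold) and NRG1, neuregulin (3.32-fold). Immediate early genes had a median of 0.53, with 5 of 19 at least 2-fold higher, among them FOSL1 (4.80-fold), ATF3 (3.78-fold) and DUSP1 (3.52-fold). Antigen presentation genes had a median of 0.55, with 3 of 19 at least 2-fold higher, namely CD74, the class II invariant chain (at least 3.53-fold), TAPBP, tapasin (3.04-fold), and HLA-B (2.13-fold). Glycolysis and hypoxia genes had a median of 0.45, with 27 of 29 above 0 and 8 at least 2-fold higher, among them NDRG1 (4.62-fold), VEGFA (3.10-fold), BNIP3 (2.90-fold) and PDK1 (2.73-fold). Each of these 6 medians was at percentile 100 of the random lists.

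Lists of focal adhesion, integrin and extracellular matrix genes were higher as well. The focal adhesion and actin list had a median of 0.39 (percentile 99.9), with 6 of 22 at least 2-fold higher, among them FERMT1, kindlin-1 (4.29-fold), ZYX, zyxin (2.41-fold), and ACTN4 (2.25-fold), and TPM1, a tropomyosin, 3.35-fold lower. Integrins and hemidesmosome genes had a median of 0.37 (percentile 99.5), with ITGA5 (2.67-fold), CD151 (2.47-fold) and ITGA3 (2.09-fold) at least 2-fold higher. Extracellular matrix genes had a median of 0.32 (percentile 99.5), with LAMB3, a laminin chain, 3.08-fold higher and SPARC lower. Apoptosis regulators (0.30, percentile 99.7) and interferon response genes (0.26, percentile 99.9) also stood higher, with MCL1 2.70-fold, BID 2.63-fold and IFI27 4.70-fold above vector. Of 31 interferon response genes, 4 were at least 2-fold higher and 2 at least 2-fold lower, and 11 were below 0. Calls for 4 more lists, higher at these settings, were each lost under at least 3 of 11 alternatives: basal keratinocyte (0.37, percentile 99.4), NRF2 and aldo-keto reductases (0.26, percentile 98.8), TGF-beta targets (0.25, percentile 98.9) and epidermal differentiation (0.19, percentile 98.5). In the epidermal list 6 of 28 genes were at least 2-fold higher and 6 lower, and its median was -0.044 with 16 added in place of a floor. The integrin call was lost with the mean of all probe sets and with probe sets specific by name, the extracellular matrix call with the mean in place of the median, and the apoptosis call with the floor at the 70th percentile.

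The 5 lists that stood lower with nm23-H2 were cholesterol and fatty acid synthesis, replication-dependent histones, proliferation, xenobiotic and retinoid metabolism, and simple epithelium. Cholesterol and fatty acid synthesis had a median of -0.57 (percentile 0), with 5 of 18 at least 2-fold lower, among them SCD, a fatty acid desaturase (3.60-fold), SREBF1, the regulator of fatty acid synthesis (3.51-fold), and INSIG1 (3.08-fold). Replication-dependent histone genes had a median of -0.73 (percentile 0), with H2BC12 (3.04-fold), H2AC6 (2.49-fold), H2BC6 (2.32-fold) and H1-2 (2.25-fold) the 4 of 10 at least 2-fold lower. Proliferation genes had a median of -0.35 (percentile 0.460), with 19 of 24 below 0 and 2 at least 2-fold lower, CENPF (at least 2.08-fold) and AURKA (2.21-fold, or 0.20 log2 higher by a probe set specific by name). Xenobiotic and retinoid metabolism (-0.43, percentile 0.710) and simple epithelium genes (-0.50, percentile 1.08) were lower, with GSTM3 and CYP1A1 in the former and KRT8, a keratin, 2.04-fold lower in the latter. Of the 8 simple epithelium genes measured, 1 was at least 2-fold lower and 1 at least 2-fold higher. Probe sets specific by name ended the cholesterol, histone and simple epithelium calls, the mean in place of the median also ended the simple epithelium call, and a floor at the 70th percentile ended the proliferation call. Differences were under 2-fold by probe sets specific by name for BNIP3 (0.69), NRG1 (0.80), MCL1 (0.41) and INSIG1 (-0.99), and by the mean of a gene's probe sets for CENPF (-0.35), DUSP1 (0.91), TAPBP (0.80), HLA-B (0.98) and TPM1 (-0.69). Of the 93 genes that the naming rule took at 2-fold or more, 14 were under it with the values as deposited, among them H2AC6, H2BC6, H1-2 and KRT8, and 13 with the floor at the 70th percentile.

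The nm23-H2 array was also brighter in its hybridisation controls. Bacterial and phage transcripts added to the sample, read by 18 probe sets, had a median difference of 0.70 from vector with nm23-H2 and -0.09 with nm23-H1, and the list of reference genes had medians of 0.21 and 0.01. With the values as deposited, 630 genes were at least 2-fold higher with nm23-H2 and 108 lower, around an all-gene median of 0.17 in place of -0.06, and with arrays scaled to a common median above the floor the split was 242 to 382, around -0.13. A floor at the 25th percentile gave 621 higher and 979 lower. Neighbouring genes shifted on chromosome 20 (NRSN2 to CST4, 347111 to 23689038, median 0.39), chromosome 9 (RLN1 to GNAQ, 5334930 to 78031811, 0.22) and chromosome 14 (KLHL28 to SLC10A1, 44924324 to 69797241, -0.37). These windows held 39 of the 573 genes at least 2-fold different (6.81%) against 2.85% of all genes placed, 36 of them in the window's direction (6.28%), TRIB3 and FERMT1 among them.

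**Figure D3:**
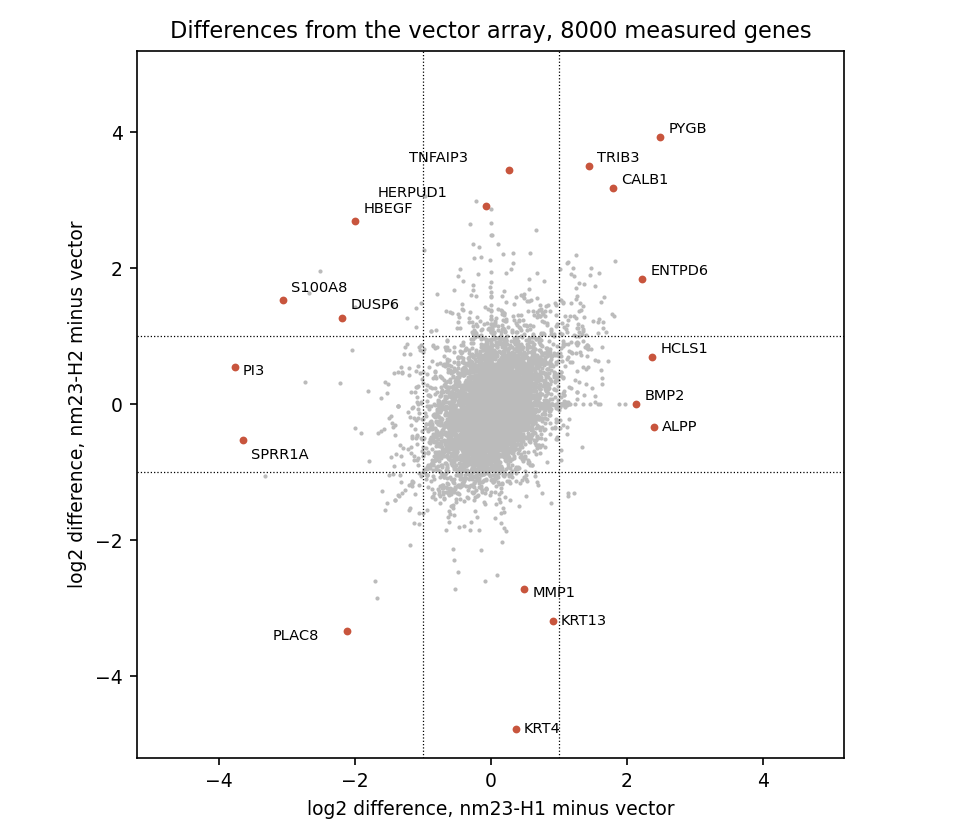
Log2 difference from vector of the 8000 measured genes, nm23-H1 on the horizontal axis and nm23-H2 on the vertical axis, 1 point per gene, with the genes named by the largest differences labelled. HBEGF was at least 3.99-fold lower with nm23-H1 and 6.45-fold higher with nm23-H2, while PLAC8 was lower with both.

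**Figure D4:**
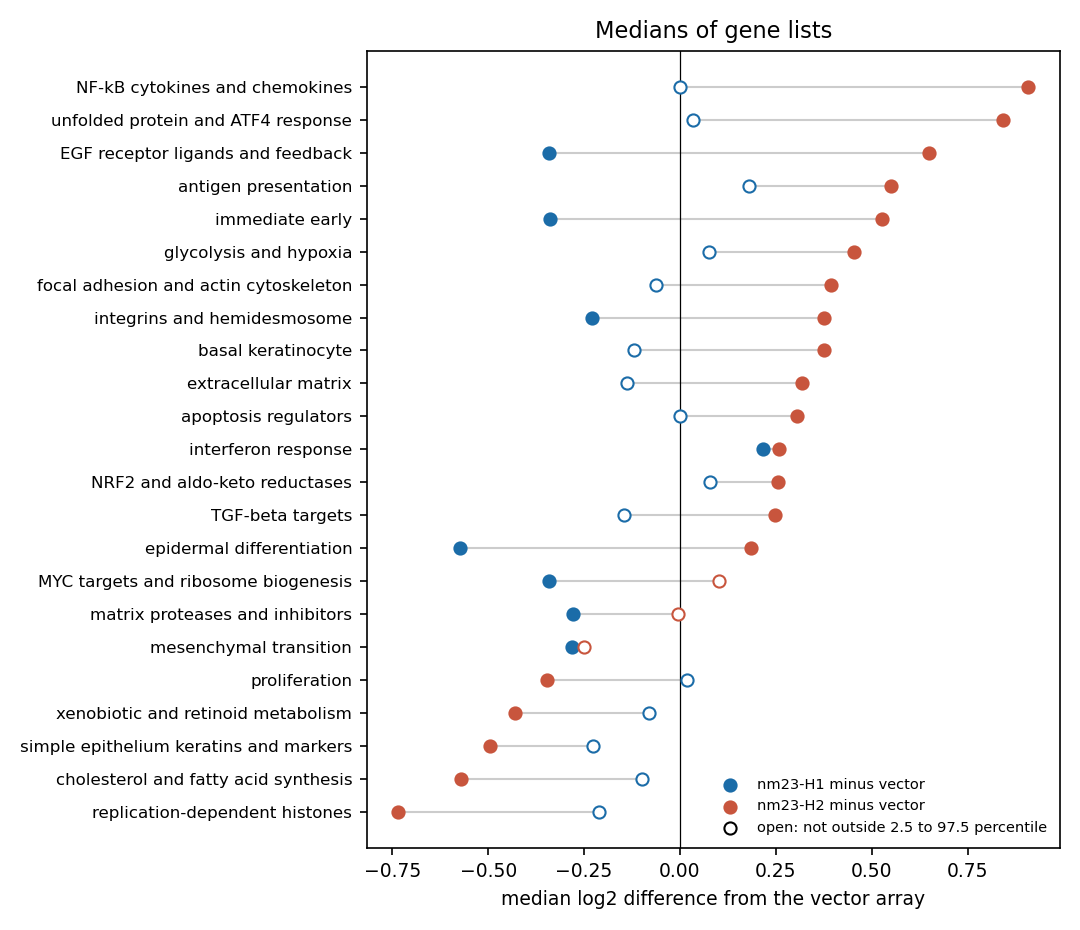
Median log2 difference for nm23-H1 against vector and nm23-H2 against vector of the gene lists that stood apart in at least 1 of these comparisons. There is 1 point per list and comparison, filled where the list stood apart from random lists. Lists that stood apart in neither are not drawn. EGF receptor ligands and feedback genes had medians of -0.34 with nm23-H1 and 0.65 with nm23-H2.

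The last comparison set the transfectants against each other. With nm23-H1, KRT4 was at least 35.3-fold higher than with nm23-H2, KRT13 17.1-fold and MMP1 9.18-fold, followed by ALPP (at least 6.64-fold), STMN1 (6.06-fold) and CRIP2 (at least 5.79-fold). Lower with nm23-H1 were HBEGF (at least 25.7-fold), S100A8 (24.0-fold), S100A9 (22.1-fold), PI3 (104 against 2086 signal units), VEGFA (at least 19.9-fold) and LCN2 (16.3-fold). Further probe sets gave smaller log2 differences for S100A8 (-0.89), VEGFA (median -1.81), PI3 (-3.73) and HBEGF (-3.94). In all, 299 genes were at least 2-fold higher and 299 lower with nm23-H1 than with nm23-H2, of which 81 and 63 were bounds. The split was 172 to 494 with the values as deposited, and 405 to 252, around an all-gene median of 0.15 in place of 0.08, with a common median above the floor, and 1087 to 634 with the floor at the 25th percentile. For 81 of 99 such genes with a further probe set (81.8%), it went the same way. Neighbouring genes shifted on chromosome 22, where the 61 genes from XPNPEP3 to ARSA (40857148 to 50628152) had a median of -0.36, and these windows held 16 of the 598 genes at least 2-fold different (2.68%) against 0.763% of all genes placed. Of the 90 genes that the naming rule took at 2-fold or more, 15 were under it by the mean of a gene's probe sets and 12 with the floor at the 70th percentile.

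Of the 38 ranked lists, 22 stood apart between the transfectants, 6 higher and 16 lower with nm23-H1. EGF receptor ligands and feedback genes had a median of -1.30, with 10 of 16 at least 2-fold lower with nm23-H1, and epidermal differentiation had -0.91, with 14 of 28 lower and 3 higher. The unfolded protein and ATF4 list had a median of -0.80 and NF-kB cytokines -0.79, with 11 of 27 and 8 of 17 genes at least 2-fold lower. Immediate early genes (-0.52), integrins (-0.51), MYC targets and ribosome biogenesis (-0.49), basal keratinocyte genes (-0.45), glycolysis and hypoxia (-0.39), focal adhesion (-0.37), metastasis suppressors (-0.36), p53 targets (-0.36), apoptosis regulators (-0.34), extracellular matrix (-0.33), antigen presentation (-0.28) and TGF-beta targets (-0.25) were lower too. TGF-beta targets turned to 0.27 with the floor at the 25th percentile and 0.17 with 16 added in place of a floor. Higher with nm23-H1 were tight and gap junction genes (0.72), histones (0.58), xenobiotic and retinoid metabolism (0.54), proliferation genes (0.40), interferon response genes (0.28) and oxidative phosphorylation (0.12). The oxidative phosphorylation median was -0.10 with the values as deposited, and the interferon call held under 3 of 11 alternatives. The calls for oxidative phosphorylation held under 5, those for TGF-beta targets and xenobiotic metabolism under 6, and those for tight and gap junction, basal keratinocyte and metastasis suppressor genes under 7. The p53 call was lost with the floor at the 70th percentile and with probe sets specific by name, which also ended the MYC, glycolysis and histone calls. The focal adhesion call was lost without the block genes and the integrin call with the mean of all probe sets.

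Genes were set apart on 1 array when it differed at least 2-fold from both others and these lay within 0.5 (log2) of each other. There were 86 for nm23-H1 (43 higher, 43 lower), 211 for nm23-H2 (111 higher, 100 lower) and 75 for vector (26 higher, 49 lower). In the same order the counts were 354, 577 and 318 with the floor at the 25th percentile, 33, 128 and 33 with the floor at the 70th, and 56, 128 and 38 with probe sets specific by name. Both other arrays were at the floor, which fixes their agreement, for 16, 18 and 10 of the higher genes, and the lower array was at the floor for 14, 21 and 7 of the lower ones. With nm23-H1 the 5 highest were ALPP, BMP2, MMP13, HSPB8 and SNCG, and the 5 lowest were SPRR1B, SPRR2B, SBF1, TSFM and ADSL, an enzyme of purine synthesis. Of these, BMP2 (0.91), MMP13 (0.74), HSPB8 (0.66), SNCG (0.38), SPRR2B (-0.59) and TSFM (-0.76) differed from vector by less than 2-fold with the floor at the 70th percentile. With nm23-H2 they were TNFAIP3, PHLDA1, HERPUD1, C3 and RHCG, and KRT4, MMP1, CYP1A1, STMN1 and GET1. On the vector array they were CPVL, DNAJC7, APOBEC3B, POGZ and VIM, and ENTPD6, THBD, LTBP2, SNX5 and GCLM, the last a subunit of the enzyme that starts glutathione synthesis. All 5 of the genes higher on the vector array were bounds against nm23-H1, at 72.4 to 83.6 signal units on vector, and nm23-H1 differed from vector by only -0.13 (VIM) to -0.34 (CPVL) in them, and by 0.44 in SNX5, with the floor at the 70th percentile.

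Across the 8000 genes, the differences of nm23-H1 and nm23-H2 from vector had a Pearson correlation of 0.332 and a Spearman correlation of 0.338, and genes are not independent replicates. Simulated arrays without any difference gave 0.50 with equal error and 0.357 with the error of each array, because both comparisons share the vector array, which could not be split. The covariance was 0.0844, against 0.0617 and 0.0400 in the simulations. Among genes at least 2-fold different in both, 66 were higher with both constructs, 34 lower with both, 11 lower with nm23-H1 and higher with nm23-H2, and 3 the reverse. Independent differences would give 6.12, 4.97, 4.85 and 6.27, and the simulated arrays with equal error, which share the vector array, gave 1.5, 2.09, 0 and 0. Whatever sets the vector array apart beyond probe error adds to the counts in the same direction, so these were not read as a shared response.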

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

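The tests of probe error and of hybridisation in this part were chosen after the results were seen, and the tests of chromosome windows were written before. The hybridisation controls, which none of the comparisons used, were brighter on the nm23-H2 array than on the vector array, by a median of 0.70 (log2) over 18 probe sets with a range of 0.41 to 0.99. The same difference for nm23-H1 was -0.09.

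For the 573 genes at least 2-fold different with nm23-H2, a stronger hybridisation or scan of that array was tested by quantile normalization, which gives the arrays the same distribution: 88.5% (507 genes, 95% exact interval 85.6 to 91.0) were still at least 2-fold different in the same direction. The values had already been scaled to a common mean, so most calls could be kept whatever the cause. Differences in distribution that remained after this scaling thus did not make most of the calls. Whether a stronger hybridisation made them was not decided, and a hybridisation difference between probe sets was not tested. Error of single probe sets was tested by the further probe sets, 90.2% of which went the same way (exact interval 82.2 to 95.4, 92 genes). That argues against such error as the source of all the calls tested, but part of them may still be error. Genes without a further probe set above the floor on both arrays were not covered. The share going the same way was lower with the floor at the 25th percentile (75.3%) and with 16 added in place of a floor (76.9%). Chromosome copy number differing between the transfectants cannot be told apart from the construct for the 6.28% (exact interval 4.44 to 8.59) that lay in shifted windows in their direction, because construct and transfectant coincide. The interval spans the 5% fixed as the bound for excluding copy number. It treats neighbouring genes as independent and measures no spread between transfectants, so it does not decide the question. The share lay between 2.42% (probe sets specific by name) and 12.5% (floor at the 70th percentile) under the alternatives. What stays open is nm23-H2 itself, any other difference between the separately grown transfectants, and the day of hybridisation, none of which the design separates.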

How the results depend on the processing

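The alternatives without the nm23-H2 array and without the block genes, and the chromosome windows under each setting, were chosen after seeing the data. Of 3988 gene values under the alternatives, 3629 moved by less than the probe error, 354 by more, and 5 turned from at least 2-fold to the opposite sign. The sign differed for 26 values in all, the smaller differences included. Of 1391 list medians, 1277 kept their place inside or outside the random lists or, in lists too short to rank, moved by less than the probe error. The others were 3 short lists that moved by more, 72 that lost and 36 that gained a place outside, and 3 that lost it and took the opposite sign. The sign differed for 83 medians in all, most of them in lists that did not stand apart. In the comparisons below, nm23-H1 and nm23-H2 stand for their difference from vector. No paired analysis was possible because each group has 1 array, for the same reason none could be left out as a replicate, and signal near the floor limits folds to bounds. The mean of a gene's probe sets leaves no pair for the probe error.

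A floor at the 25th percentile (10691 genes) gave 653 genes at least 2-fold higher and 552 lower for nm23-H1, 621 and 979 for nm23-H2, and 1087 and 634 for nm23-H1 against nm23-H2. Genes set apart numbered 354, 577 and 318 for nm23-H1, nm23-H2 and vector, the correlation of both differences from vector was 0.398, probe error SDs were 0.51, 0.53 and 0.57, and the further probe set went the same way in 68.1% and 75.3%. A floor at the 70th percentile (5045 genes) gave 72 and 59 for nm23-H1, 112 lower for nm23-H2, 113 and 192 for nm23-H1 against nm23-H2, 33, 128 and 33 set apart, a correlation of 0.282, probe error SDs of 0.26, 0.31 and 0.32, and 95.5% and, for nm23-H1 against nm23-H2, 92.3% going the same way. With 16 added in place of a floor (11963 genes), the correlation was 0.365, the probe error SDs for nm23-H1 and nm23-H2 0.38 and 0.41, and 69.0% and 76.9% went the same way. The counts follow from the number of genes and the height of the floor; for the correlations, probe errors and shares the cause was not tested.

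Probe sets specific by name (4917 genes measured, fewer by construction) gave 109 higher and 76 lower for nm23-H1, 163 and 168 for nm23-H2, 178 and 169 for nm23-H1 against nm23-H2, 56, 128 and 38 set apart, probe error SDs of 0.37, 0.41 and 0.46, and 13 lists apart for nm23-H1 against nm23-H2; for the probe errors and lists the cause was not tested. With the values as deposited, 630 were higher and 108 lower for nm23-H2 and 172 and 494 for nm23-H1 against nm23-H2, and 56 were set apart for nm23-H1. Before scaling the nm23-H2 array had the highest mean signal. Why the genes set apart for nm23-H1 were fewer was not tested. A threshold of 1.5 gave 33 and 29 for nm23-H1, 85 and 46 for nm23-H2, 55 and 108 for nm23-H1 against nm23-H2, and 14, 50 and 7 set apart. Leaving out the block genes gave 115 higher for nm23-H1.

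The results that lost their call, or their 2-fold difference, and took the opposite sign were these. The median of the list epidermal differentiation for nm23-H2 was -0.044 with 16 added in place of a floor. The median of the list TGF-beta targets for nm23-H1 against nm23-H2 was 0.27 with the floor at the 25th percentile and 0.17 with 16 added. With probe sets specific by name, AURKA for nm23-H2 was 0.20, PARVA for nm23-H1 -0.27, and for nm23-H1 against nm23-H2 MCL1 was 0.17 and RRP12 0.036. Without the nm23-H2 array, IL1RN for nm23-H1 was 0.012. In these 5 genes another probe set of the gene was read. For the list medians the cause was not tested.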

Other observations

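The gene groups whose medians are given in this paragraph did not stand apart from random lists in either comparison with vector. Further lists are named below only for a change of sign. Of these, focal adhesion, cholesterol and xenobiotic stood apart with nm23-H2 and matrix proteases with nm23-H1. Nucleotide synthesis genes, which include partners of nucleoside diphosphate kinases, had medians of 0.04 with nm23-H1 and 0.14 with nm23-H2, with DTYMK, thymidylate kinase, 2.59-fold and 2.44-fold higher, PFAS 2.38-fold and 2.41-fold higher, and ADSL, in the shifted block of chromosome 22, 3.06-fold lower with nm23-H1 (-0.65 log2 by its other probe set). Desmosome and adherens junction genes had medians of -0.13 and -0.01, tight and gap junction genes 0.03 and 0.03 (with nm23-H1, CLDN1 2.15-fold and CLDN4 2.09-fold higher, 2 of 7), Wnt targets -0.06 and -0.01, p53 targets -0.12 and 0.14, DNA replication genes -0.02 and -0.22, and metastasis suppressors -0.25 (percentile 2.87) and -0.14. In the last list TXNIP was 2.19-fold higher with nm23-H1 and 2.48-fold lower with nm23-H2, and NDRG1 4.62-fold higher with nm23-H2. Among DNA replication genes PCNA, in the shifted block of chromosome 20, was higher by 1.58 (log2) with nm23-H1, and among p53 targets GADD45A was 4.49-fold and CDKN1A 2.55-fold higher with nm23-H2. Ribosomal proteins had medians of -0.09 and 0.13, oxidative phosphorylation 0.04 and -0.07, heat shock genes -0.05 and -0.27 (percentile 3.48), and metallothioneins -0.06 and -0.03. With the values as deposited, the Wnt, DNA replication, heat shock, ribosomal protein, metallothionein, focal adhesion, cholesterol, xenobiotic and Nm23-H1-linked medians of nm23-H1 changed sign, as did those of desmosome and adherens junction, Wnt, matrix protease, metallothionein, metastasis suppressor, DNA replication, oxidative phosphorylation, heat shock and cancer-testis genes of nm23-H2. Quantile normalization turned the metallothioneins of nm23-H1 and the ribosomal proteins and desmosome genes of nm23-H2, and other floors or probe sets turned further medians.

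With nm23-H2 the matrix protease list (-0.01), the mesenchymal list (-0.25), the ribosome biogenesis list (0.10) and the genes linked elsewhere to Nm23-H1 (-0.15) did not stand apart, although MET was 2.20-fold higher (0.48 log2 by the mean of its probe sets) and SMO 2.82-fold lower. With nm23-H1 the unfolded protein (0.03), NF-kB (0), antigen presentation (0.18), glycolysis (0.08), cholesterol (-0.10), histone (-0.21), apoptosis (0), extracellular matrix (-0.14), focal adhesion (-0.06), basal keratinocyte (-0.12), simple epithelium (-0.23), proliferation (0.02), TGF-beta (-0.14), NRF2 (0.08) and xenobiotic (-0.08) lists did not. Cancer-testis antigens had medians of 0 and -0.13. Markers of other cell types were within 2-fold of vector, with medians for leukocytes of 0.23 and -0.16, for fibroblasts of 0.41 and 0.06 over 4 genes, and for endothelium of 0.39 and 0 over 3 genes. The ratio of the 3' to the 5' probe set of ACTB was 1.41 with nm23-H1, 1.90 with nm23-H2 and 1.75 with vector, and that of GAPDH 0.878, 1.04 and 0.881.

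Among the tests below, those of probe error, hybridisation and glucose, and that of copy number for the unfolded protein genes, were chosen after the results were seen. For the 310 genes at least 2-fold different with nm23-H1, error of single probe sets was tested by the further probe sets. Of these, 86.0% went the same way (exact interval 74.2 to 93.7, 57 genes). That argues against such error as the source of all the calls tested, but part of them may still be error. Genes without a further probe set above the floor on both arrays were not covered. The share going the same way was 68.1% with the floor at the 25th percentile and 95.5% with the floor at the 70th. It was 69.0% with 16 added in place of a floor. Chromosome copy number differing between the transfectants may account for part of the 310 genes, since 26.8% (exact interval 21.9 to 32.1) lay in shifted windows in the window's direction, past the 25% fixed beforehand. The interval spans that 25%, and it treats neighbouring genes as independent, which they are not. The same share was 9.88% with the floor at the 25th percentile, 47.3% with the floor at the 70th and 16.6% with 16 added in place of a floor, so whether it passes 25% depends on the floor. For the 221 genes outside the windows, nm23-H1 and other differences between the transfectants stay open and were not tested.

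The unfolded protein and ATF4 genes that were higher with nm23-H2 kept a median of 0.94 after quantile normalization. A difference in signal distribution between the arrays thus did not make this median, but the main values already had a common mean. Hybridisation differing between probe sets was not tested, so a stronger hybridisation of that array stays open. For copy number, 7.69% of the 13 unfolded protein genes at least 2-fold higher, namely TRIB3, lay in a window of higher neighbours (exact interval 0.195 to 36.0). Shifted windows held 2.85% of all genes placed. Broad shifted blocks thus did not hold most of these 13 genes. A gain of fewer genes need not shift a window of 50, so copy number was not excluded. Less glucose in the culture at harvest is a candidate explanation that cannot be told apart from the construct with 1 culture each: TXNIP, whose transcript falls when glucose runs short, differed by -1.31 (log2), or -0.98 with the values as deposited. An effect of nm23-H2 itself stays open and was not tested.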
